A study of Rattus norvegicus with 17 samples.

How the data were processed

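Total RNA was sequenced from the left kidneys of 17 male Sprague Dawley rats. Per the labels' protocols, the rats arrived at 9 weeks of age, were fed a 0.4% Dyets chow, were operated on at 10 weeks and gave up the left kidney 6 weeks later. The 5/6Nx group (6 rats) lost the right kidney and most of the left one, the 1/3Nx group (6 rats) lost the same part of the left kidney and kept the right one, and the sham group (5 rats) kept both. Per the labels, RNA was extracted with Trizol, libraries were prepared with a TruSeq stranded total RNA kit and sequenced from both ends on an Illumina HiSeq instrument. The protocol text also calls these libraries small RNA, and that wording was not settled.

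The submitters' processing notes name cutadapt, FastQC, TopHat2 version 2.1.1, StringTie, Cufflinks version 2.2.1 and the genome build rn5, with no role or order given. The authors deposited 4 expression tables, a gene and an isoform table for each surgery against sham. Each holds 1 FPKM value per group, a log2 fold change of surgery over sham, a p-value, a q-value and a call, all made by the authors per the file headers. FPKM is the number of fragments per kilobase of feature and per M mapped fragments (SI prefix mega), scaled by the authors within each table. The column layout is the one that Cuffdiff, a program of the Cufflinks suite, writes, and the exact command is not given in the sources used here. The deposited sequencing summary gives a count of reads for each library, the percent of bases of quality 30 or more, a mean quality score and the percent of reads mapped, as the authors recorded them per the file headers. Some sequence names in the tables belong to assemblies later than rn5, so the build behind the coordinates is not settled and positions are printed as the deposited tables give them.

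Both gene tables list the same 126306 features, of which 31195 carry 1 gene name, 628 carry several names, 26 carry a name that a spreadsheet had turned into a date and 94457 carry no name. Features with several names or a date were kept out of the named genes and the gene lists. Among 12563 features, the sham values of the 1/3Nx table were 2.01 times those of the 5/6Nx table, a constant factor on the log2 scale (mean ratio -1.00, SD 0.00540 over features). Levels are therefore compared within a table. Across tables, differences of deposited log2 fold changes are given, with no test.

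A test on single libraries had been planned before the data were examined, using limma on log2 FPKM with a pseudocount, and camera for gene lists. The expression tables hold group values, so the values behind each library were not analysed here, and the plan's fallback was used: the authors' deposited log2 fold changes, p-values and q-values are reported, with q under 0.05 as the threshold. No SD, standard error or number of animals can be set beside a group FPKM. The deposited q-values were recomputed with the Benjamini-Hochberg method over all tested features and differed by at most 5.25e-07. Because the threshold depends on how many features pass, the highest p-value still called was 0.02895 in the 5/6Nx gene table and 0.0032 in the 1/3Nx gene table. Calls were therefore also recomputed from the deposited p-values over named genes alone, an alternative chosen after the data were seen.

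For the gene lists, 37 lists of kidney cell types, pathways and other tissues with 768 genes were fixed before the data were examined, of which 684 genes had a feature of their own. Members with a mean FPKM of at least 1 over the groups of a table were used. Beside the counts of members passing the authors' test, the counts adjusted over the list alone are given. The median log2 fold change of each list with at least 5 members was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. A median outside the middle 95% of random lists is reported as outside the random range; this describes these group values, is not a test across animals, and was chosen after the tables were found to hold group values. The method was tried on simulated lists of 20 genes, after shuffling the fold changes across genes. For the 11076 genes of the 5/6Nx table, 4.50% of unshifted lists and 69.5% of lists shifted by 0.5 on the log2 scale fell outside. Shuffling removes any trend with FPKM and any shared regulation of list members, so these shares may not hold for lists of co-regulated genes. For the 11599 genes of the 1/3Nx table these shares were 2.50% and 99.5%.

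The named genes follow a rule fixed before the data were examined. It leaves out placeholder names, such as LOC, RGD or assembly identifiers, uses 1 feature per gene name, and takes the 10 largest rises and the 10 largest falls past the threshold with at least 5 FPKM in the higher group, up to 4 members per gene list by smallest p-value, and 22 genes always named. Ties in the p-value, which has a floor of 5e-05 in these tables, were broken by alphabet. The part of the rule that asked for groups without overlapping libraries could not be applied to group values. Genes listed at 0 in sham have no fold change and were not ranked, a choice made after the data were seen. Egf, one of the 22 genes, has no feature under that symbol, and Col3a1 shares its feature with a second name. Some genes that the rule names are not reported here; they remain in the counts and list medians.

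Read totals ranged from 59.0 to 103.557 M reads per library, and 37.7 to 79.9 M reads mapped. Library measures were compared between groups with two-sided exact permutation tests of the means, with Benjamini-Hochberg adjustment over 12 tests, which were chosen after the data were seen. Alternatives tried were a pseudocount of 0.1 or 1, a mean FPKM of at least 5, no filter, and q-values recomputed over subsets of features. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Marker lists for pancreas, liver and plasma cells were written after some of these genes had been noticed, and the markers used to notice the pattern were kept apart from those held out.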

Results

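Subtotal nephrectomy in the rat removes kidney mass and leaves a remnant, and is used to study how the remaining tissue responds. Here the left kidney of 17 rats was profiled 6 weeks after surgery. In the 5/6Nx group (n = 6) the remnant was the only kidney tissue, in the 1/3Nx group (n = 6) the intact right kidney stayed in place, and the sham group (n = 5) lost no tissue. The labels describe separate animals.

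The number of reads per library, in M reads (SI prefix mega), was 71.9 ± 16.4 (SD, n = 6) in 5/6Nx, 70.3 ± 9.27 (SD, n = 6) in 1/3Nx and 71.4 ± 4.59 (SD, n = 5) in sham. Reads mapped at 82.7% ± 10.99 (SD, n = 6), 89.0% ± 1.16 (SD, n = 6) and 87.7% ± 1.94 (SD, n = 5), in the same order. The wide spread in 5/6Nx came from replicate 3 at 62.6% and replicate 5 at 77.2%, while the other 4 libraries of the group lay between 87.0% and 90.5%. A two-sided exact permutation test detected no difference in mapping rate between 5/6Nx and sham (p = 0.422, adjusted p = 0.569 over 12 tests). Bases of quality 30 or more made up 81.6% of replicate 3 and 86.3% of replicate 5 of 5/6Nx, against 88.8% to 90.6% in sham.

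**Figure D1:**
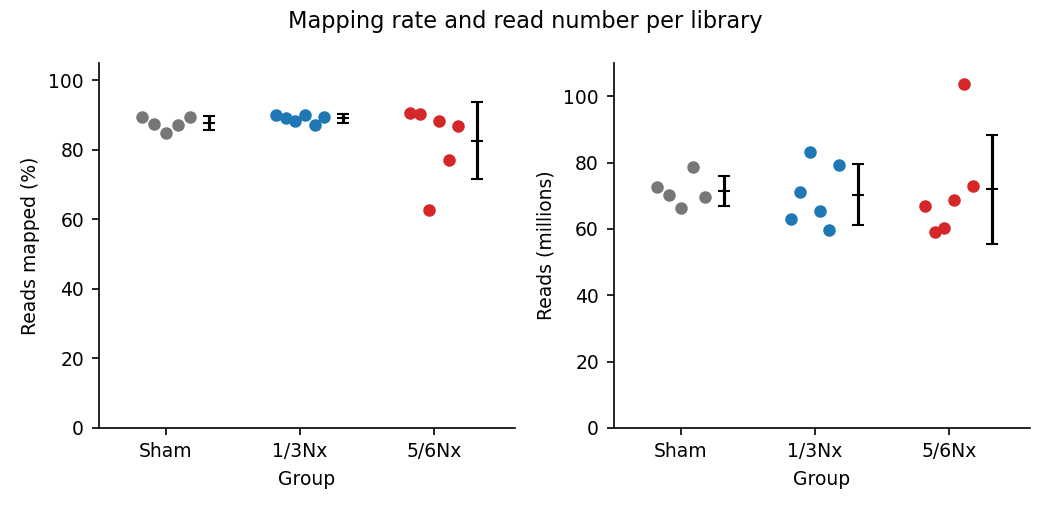
Left, percent of reads mapped and right, number of reads in M reads, for each library of the sham, 1/3Nx and 5/6Nx groups; points are libraries and the bar beside them is the mean with 1 SD. Replicate 3 of 5/6Nx lies at 62.6% mapped, and replicate 5 of 5/6Nx holds 103.557 M reads.

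The first comparison asks how the remnant left kidney differed from sham when the right kidney was kept (1/3Nx). Many matrix, injury and immune genes rose and some metabolic genes fell. In the authors' deposited table, 1358 of 21217 tested features passed, 841 higher and 517 lower. Of 13326 tested features with 1 gene name, 1110 passed, 760 higher and 350 lower. Among the genes always named, Havcr1, the kidney injury molecule of damaged proximal tubule, rose from 1.20 to 13.9 FPKM (log2 fold change 3.53, q = 0.00183) in the authors' deposited table. Lcn2, which encodes the injury marker NGAL, rose from 9.90 to 83.6 FPKM (log2 fold change 3.08, q = 0.00183), and Spp1, which encodes osteopontin, reached 1729 FPKM (log2 fold change 2.09, q = 0.00183), per the authors' deposited table. This q of 0.00183 is the smallest the table holds, since its p-values have a floor of 5e-05. The authors' deposited table lists the feature of Havcr1 at 31813813 to 31848379 on chromosome 10. It lists that of Lcn2 at 11414185 to 11417683 on chromosome 3 and that of Spp1 at 6673685 to 6696879 on chromosome 14. The build behind these positions is not settled, and a listed interval may be wider than the gene.

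Extracellular matrix genes rose. Of 27 measured members, 21 rose, 0 fell and 6 did not pass (24 rose when adjusted over the list alone), and the list median of 1.70 lay above all 10000 random lists. Per the authors' deposited table, the fibrillar collagen genes Col1a1 (log2 fold change 2.32), Col5a1 (1.70) and Col5a2 (1.91) rose, with the proteoglycan gene Bgn (1.17). The feature shared by Col3a1 and a second name rose by 2.17 and Fn1, which encodes fibronectin, by 1.90 in the authors' deposited table. Timp1, a metalloproteinase inhibitor, went from 10.7 to 41.6 FPKM in the authors' deposited table and did not pass (log2 fold change 1.95, q = 0.352). In the list of mesangium, pericytes and smooth muscle 12 of 14 members rose (13 adjusted over the list alone). They include Acta2 (1.63), which encodes smooth muscle actin, and the pericyte gene Mcam (1.44), in the authors' deposited table. TGF-beta and BMP signalling had 5 risers among 23 (8 rose and 1 fell when adjusted over the list alone). Among them were Tgfb3 (2.15), Tgfb1 (0.89) and the latent TGF-beta binding protein gene Ltbp2 (2.25), per the authors' deposited table.

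Genes of tubular injury and dedifferentiation rose in 15 of 23 cases (18 rose and 1 fell when adjusted over the list alone). In the authors' deposited table the hyaluronan receptor gene Cd44 rose by 2.73 on the log2 scale, the annexin genes Anxa1, Anxa2 and Anxa3 by 1.63, 1.25 and 1.02, and the intermediate filament gene Vim by 1.46. Cdkn1a, a cell cycle inhibitor induced by p53, had a log2 fold change of 0.75 that did not pass (q = 0.183) in the authors' deposited table. Immediate early genes rose in 9 of 16 cases (13 adjusted over the list alone), with Fos at 2.14, Fosb at 2.26, Atf3 at 1.79 and Cyr61 at 0.86 in the authors' deposited table. In the unfolded protein response and heat shock list 4 of 17 members rose (9 adjusted over the list alone). Among them the ER chaperone gene Hspa5 rose by 0.93 and the heat shock gene Hsph1 by 0.80 in the authors' deposited table. Of 16 p53 targets 2 rose (2 adjusted over the list alone), among them Btg2 (0.81), and of 15 cell cycle genes 1 rose (1 adjusted over the list alone), Mcm3 (1.43), per the authors' deposited table.

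Immune cell markers were higher. Of 19 macrophage and monocyte markers 15 rose (15 adjusted over the list alone), including Cd68 (1.49), Adgre1 (1.24), Cd14 (1.31) and C1qb (1.34) in the authors' deposited table. Of 14 lymphocyte markers 7 rose (10 adjusted over the list alone), and the T cell receptor complex genes Cd3e and Cd3g rose by 2.85 and 2.41 in the authors' deposited table. Complement genes rose in 9 of 13 cases (9 adjusted over the list alone), with C6 at 3.99, C7 at 1.85, C1s at 1.82 and C3 at 1.78 in the authors' deposited table. Liver also makes complement proteins, and the liver gene Alb rose by 5.04 in the authors' deposited table. Of 20 cytokine, chemokine and adhesion genes 8 rose (15 adjusted over the list alone). The monocyte chemokine gene Ccl2 rose by 1.87 and the lymphoid chemokine genes Ccl19 and Ccl21 by 2.82 and 2.79 in the authors' deposited table. The interferon response list had 3 risers of 21 (7 adjusted over the list alone): Gbp2 (1.31), Irf1 (1.19) and Cxcl9 (1.52) in the authors' deposited table. Antigen presentation had 1 riser of 11 (4 adjusted over the list alone), the class II gene RT1-Da (0.81), per the authors' deposited table. Of these 11 genes 10 had higher values, and the list median of 0.53 (percentile 99.98) lay outside the random range. None of 3 neutrophil and mast cell markers passed in the authors' test, and 1 had an unadjusted p under 0.05.

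Some metabolic genes fell. Of 29 genes of gluconeogenesis, amino acid and organic acid metabolism 7 fell (12 adjusted over the list alone), with a list median of -0.59 below all 10000 random lists. The serine synthesis genes Phgdh, Psat1 and Psph had log2 fold changes of -0.90, -0.95 and -0.94, and Haao, an enzyme of tryptophan breakdown, had -1.02, in the authors' deposited table. Of 30 fatty acid oxidation and peroxisome genes 5 fell (5 adjusted over the list alone), such as the acyl-CoA dehydrogenase gene Acads (-0.82), per the authors' deposited table. Of 30 nuclear oxidative phosphorylation genes 6 fell (14 adjusted over the list alone), among them Atp5g1 (-0.89) and Cox5a (-0.79) in the authors' deposited table. That list's median of -0.50 lay at percentile 3.85 of random lists, inside their range, as random lists of like FPKM had a median of -0.35. Of 32 proximal tubule genes 6 fell (10 fell and 1 rose when adjusted over the list alone), and the list median of -0.40 lay at percentile 3.58, inside the random range. The organic anion transporter gene Slc22a6 fell by 0.81, the urate transporter gene Slc22a12 by 0.96 and Ggt1 by 0.94 on the log2 scale in the authors' deposited table. The phosphate transporter gene Slc34a1 (-0.79, q = 0.183) and the endocytic receptor gene Cubn (-0.21, q = 0.724) did not pass in the authors' deposited table.

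Few markers of the other nephron segments passed. Of 16 thick ascending limb genes 1 fell (1 adjusted over the list alone), Cryab (-0.84), while Umod, the uromodulin gene, had a log2 fold change of -0.18 (q = 0.829) in the authors' deposited table. Of 14 distal convoluted and connecting tubule genes 1 rose (1 adjusted over the list alone), the calcium channel gene Trpv5 (1.54), and Kl, which encodes klotho, was at -0.05 (q = 0.937), per the authors' deposited table. In the collecting duct, 0 of 16 principal cell genes and 0 of 13 intercalated cell genes passed the authors' test, with 3 and 1 at an unadjusted p under 0.05. Podocytes had 1 fall and 1 rise among 15 genes (the same numbers adjusted over the list alone), and Nphs1 was at -0.08 (q = 0.899), in the authors' deposited table. Endothelium had 1 rise, Cdh5 (1.03), and 1 fall, Vwf (-1.12), among 18 genes (2 rises and 1 fall adjusted over the list alone), per the authors' deposited table. Of these 18 endothelial genes 15 had higher values, and the list median of 0.30 (percentile 99.7) lay outside the random range. Of 12 renin-angiotensin genes 0 passed and 5 had an unadjusted p under 0.05, with the angiotensinogen gene Agt at -0.55 (q = 0.153) in the authors' deposited table.

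Some members of other lists changed. Of 17 circadian clock genes 3 rose and 2 fell (the same numbers adjusted over the list alone), with Cry1 at 1.74, Per3 at 0.87, Npas2 at -2.19 and Arntl at -1.14 in the authors' deposited table. Values were higher for 13 of the 17 clock genes, and the list median of 0.41 (percentile 99.7) lay outside the random range. Cholesterol and fatty acid synthesis had 3 risers of 21 (4 adjusted over the list alone), among them Hmgcs1 (0.76) and Fasn (0.75), per the authors' deposited table. Of 15 genes of ion and mineral hormones 2 rose, the endothelin gene Edn1 (1.35) and its receptor gene Ednra (1.34), and 1 fell, the parathyroid hormone receptor gene Pth1r (-0.88), in the authors' deposited table, with the same numbers adjusted over the list alone. Of 22 xenobiotic and glutathione genes 1 rose, the heme oxygenase gene Hmox1 (2.04), and 2 fell, Gstp1 (-0.77) and Gpx1 (-0.91), in the authors' deposited table (1 rise and 3 falls adjusted over the list alone). Of 22 glycolysis and hypoxia genes 1 rose, Hk2 (1.17), per the authors' deposited table (1 adjusted over the list alone). The only measured mitochondrially encoded gene, Mt-nd1, was at 0.01 (q = 0.996) in the authors' deposited table.

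Markers of other tissues moved with the surgery. The 10 largest rises were genes of the exocrine pancreas, led by Prss3 (log2 fold change 9.74), the pancreatic lipase gene Pnlip (9.55), the carboxypeptidase gene Cpb1 (9.06) and the elastase gene Cela2a (9.06) in the authors' deposited table. Sycn, Pnliprp1, Cela3b, Cpa1 and Cel were among the rest, with log2 fold changes of 7.91 to 8.90 in the authors' deposited table. Each of the 10 had under 0.4 FPKM in sham. Of 6 urothelial markers 4 rose (4 rose and 1 fell when adjusted over the list alone), such as Upk1b (2.12) and Upk2 (1.86), and of 6 skeletal muscle markers 3 rose (4 adjusted over the list alone), such as Acta1 (2.15), per the authors' deposited table. Of 11 adipocyte markers 2 rose (2 adjusted over the list alone), Car3 (1.98) and Fabp4 (1.28), in the authors' deposited table. None of 4 erythrocyte and 2 adrenal markers passed the authors' test, also at an unadjusted p under 0.05. Among the 10 largest falls were Slc22a13 (-2.01), Tmem86a (-1.95), Tcea3 (-1.65), Tex101 (-1.57), Prima1 (-1.46), Kcp (-1.42), Pgam2 (-1.41), Ttll8 (-1.39) and Ttc36 (-1.38) in the authors' deposited table.

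**Figure D2:**
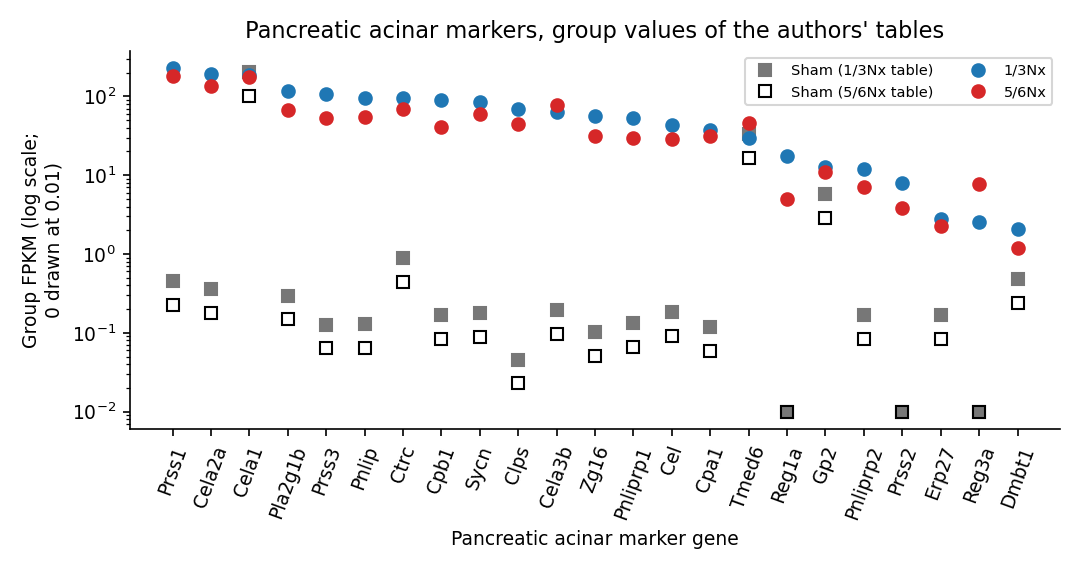
Group FPKM on a log axis for the pancreatic acinar markers reported here with at least 1 FPKM in 1/3Nx, as the authors' deposited tables give them, with values of 0 drawn at 0.01. Circles are 1/3Nx and 5/6Nx, and squares are sham in either table; most circles lie far above the squares, while Cela1 and Tmed6 are also high in sham.

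The second comparison asks how the remnant differed from sham when it was the only kidney tissue (5/6Nx). Injury, matrix and several immune lists had higher values, and markers of several nephron segments had lower values, but few members of these lists passed. In the authors' deposited table, 60264 of 103823 tested features passed, 60122 higher and 142 lower. Most of these were not genes with a name: 58038, or 96.3%, were unnamed loci listed at 0 in sham, with a median span of 257 bp. Of 14452 tested features with 1 gene name, 1171 passed, 1158 higher and 13 lower, and 591 passed when q-values were recomputed over these features alone. Of the 1171 named features that passed, 416 were listed at 0 in sham, like the unnamed loci above. Of 10068 tested features with 1 gene name and at least 1 FPKM in sham, 171 passed, 161 higher and 10 lower, and 35 passed on recomputing. The median log2 fold change of these 10068 features was -0.20. Because the many passing loci relax the threshold for every feature, calls recomputed over named genes are given as well. That recomputation still includes the named features listed at 0 in sham, which relax the threshold too.

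Several injury genes passed. Havcr1 rose from 0.596 to 21.4 FPKM (log2 fold change 5.16, q = 0.00195, recomputed q = 0.0292) in the authors' deposited table. Of 20 injury and dedifferentiation genes 4 rose (3 adjusted over the list alone) and 19 had higher values, with a list median of 1.11 outside the random range. Besides Havcr1 these were Fgb (4.15), which encodes fibrinogen beta, Cdkn1a (3.25) and Lcn2 (3.77), in the authors' deposited table. Recomputed q-values over named genes were 0.0168 for Fgb, 0.0647 for Cdkn1a and 0.308 for Lcn2. Spp1 (2.88, q = 0.134) and Vim (2.00, q = 0.385) did not pass in the authors' deposited table. Of 16 p53 targets 2 rose (2 adjusted over the list alone), Cdkn1a and the kinase gene Plk2 (6.68, recomputed q = 0.0458), per the authors' deposited table. Of 14 cell cycle genes 5 rose (1 adjusted over the list alone), with examples Nusap1 (3.23), the replicative helicase gene Mcm6 (4.58), the topoisomerase gene Top2a (3.63) and the cyclin gene Ccne1 (4.20) in the authors' deposited table. On recomputing over named genes 1 of the 5, Nusap1, stayed past the threshold.

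Matrix genes had higher values, and few matrix or immune genes passed. Of 23 matrix genes 22 had higher values, with a list median of 1.53 above all 10000 random lists, and 2 rose (0 adjusted over the list alone). These were the elastin gene Eln (2.48, q = 0.00966, recomputed q = 0.115) and Timp1 (2.28, q = 0.0461, recomputed q = 0.339), per the authors' deposited table. Col1a1 (2.21, q = 0.243), the feature of Col3a1 and a second name (1.93, q = 0.323) and Fn1 (1.57, q = 0.201) did not pass in the authors' deposited table. Of 17 macrophage and monocyte markers 1 rose (0 adjusted over the list alone), Trem2 (3.08), and Cd68 was at 1.06 (q = 0.301), in the authors' deposited table. Of 9 lymphocyte markers 1 rose (0 adjusted over the list alone), Klrd1 (6.92), a receptor gene of natural killer cells, per the authors' deposited table. Complement had 2 risers of 12 (1 adjusted over the list alone), the complement factor D gene Cfd (5.12), which is also in the adipocyte list, and C3ar1 (3.41), and C3 was at 1.87 (q = 0.161), in the authors' deposited table. Cytokines, chemokines and adhesion had 2 of 18 (0 adjusted over the list alone), Ccl3 (3.18) and Ccl19 (3.66), and Ccl2 was at 0.83 (q = 0.589), per the authors' deposited table. Antigen presentation had 1 of 10 (0 adjusted over the list alone), the costimulatory gene Cd86 (2.68), in the authors' deposited table. Immediate early genes had 1 of 16 (1 adjusted over the list alone), Fosb (3.83, recomputed q = 0.0467), and TGF-beta and BMP signalling 1 of 23 (0 adjusted over the list alone), Ltbp2 (3.10), per the authors' deposited table. Of the 23 TGF-beta and BMP genes 8 had higher values, with a list median of -0.13 (percentile 37.7) inside the random range, and Tgfb1 was at 0.95 (q = 0.598) in the authors' deposited table. On recomputing over named genes, Cfd and Fosb were the only risers of this paragraph that stayed past the threshold.

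Most nephron markers had lower values and none passed. The thick ascending limb list had a median of -1.04, below all 10000 random lists, with Umod at -1.23 (q = 0.454) and the sodium transporter gene Slc12a1 at -1.10 (q = 0.291) in the authors' deposited table. The 12 intercalated cell markers all had lower values (median -0.67, percentile 0.01). The proximal tubule list had a median of -0.58, below all 10000 random lists (6 of 32 higher), with Slc34a1 at -0.17 (q = 0.901), Cubn at -0.07 (q = 0.976), Slc22a6 at 0.15 (q = 0.934) and Slc7a13 at -2.84 (q = 0.191) in the authors' deposited table. Distal convoluted and connecting tubule genes had a median of -0.44 (percentile 1.11, 4 of 14 higher), with Kl at -1.04 (q = 0.538) and Trpv5 at 1.99 (q = 0.153) in the authors' deposited table. The renin-angiotensin list had a median of -0.56 (percentile 0.250), with Agt at 0.30 (q = 0.873) in the authors' deposited table. Gluconeogenesis and amino acid genes (-0.48), oxidative phosphorylation genes (-0.39) and fatty acid oxidation genes (-0.37) also had medians outside the random range. Inside it lay principal cells (-0.30, 3 of 13 higher), podocytes (-0.28, 5 of 15 higher, with Nphs1 at -0.66, q = 0.692, in the authors' deposited table), glycolysis and hypoxia (-0.30), endothelium (-0.07) and mesangium, pericytes and smooth muscle (0.75). The interferon (0.08), unfolded protein (-0.00), circadian (0.00) and ion and mineral hormone (0.01) lists also lay inside it. With no filter the principal cell median was -0.50 (percentile 0.340), and with a pseudocount of 1 the mesangium list lay at percentile 97.7, both outside. With the neutrophil, mitochondrial, erythrocyte, adrenal and urothelial lists, these are the 22 lists of which 0 members passed the authors' test; of their 329 tested members, 2 had an unadjusted p under 0.05.

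Members of other lists changed too. Cyp2c11, a male-specific cytochrome P450 gene, fell by 3.82 on the log2 scale (q = 0.0151, recomputed q = 0.161) and Hmox1 rose by 3.41 (recomputed q = 0.339) in the authors' deposited table, as the 2 changes among 22 xenobiotic and glutathione genes (0 adjusted over the list alone). Cholesterol and fatty acid synthesis had 1 riser of 21, Scd1 (3.52, recomputed q = 0.139), per the authors' deposited table (0 adjusted over the list alone). Among other tissues, 3 of 8 adipocyte markers rose (3 adjusted over the list alone), Cfd, the adiponectin gene Adipoq (4.10) and the resistin gene Retn (3.20), in the authors' deposited table. The list median of 1.97 (percentile 99.4) lay outside the random range, as did 1.06 (percentile 97.7) with no filter, and 1 of the 3, Cfd, stayed past the threshold on recomputing. Of 3 skeletal muscle markers 1 rose (1 adjusted over the list alone), Tnni2 (4.87, recomputed q = 0.00309), per the authors' deposited table. The median of 5 erythrocyte markers was -1.07 (percentile 0.02), with the globin gene Hba-a1 at -1.33 (q = 0.364) in the authors' deposited table.

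The largest rises in 5/6Nx were genes near 0 in sham: Stmn2, Mfrp, Chgb, Stard9, Grin1, Kntc1, Mmp3, Kirrel2, Gfap and Rspo3, with log2 fold changes of 10.39 to 12.65 in the authors' deposited table. Stard9, Grin1, Kntc1 and Kirrel2 stayed past the threshold on recomputing over named genes, and the other 6 did not. A further 67 genes within the rule passed with at least 5 FPKM in 5/6Nx and are listed at 0 in sham, 44 of them olfactory receptor genes. The falls within the rule, which leaves out placeholder names, were Cyp2c11, the calcium channel subunit gene Cacng5 (-3.52), Prima1 (-2.83), the glucagon receptor gene Gcgr (-1.86) and the prolactin receptor gene Prlr (-1.70) in the authors' deposited table, and none of the 5 passed on recomputing. Which 5/6Nx libraries carry these values, and the counts without replicates 3 and 5, cannot be given from group values.

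**Figure D3:**
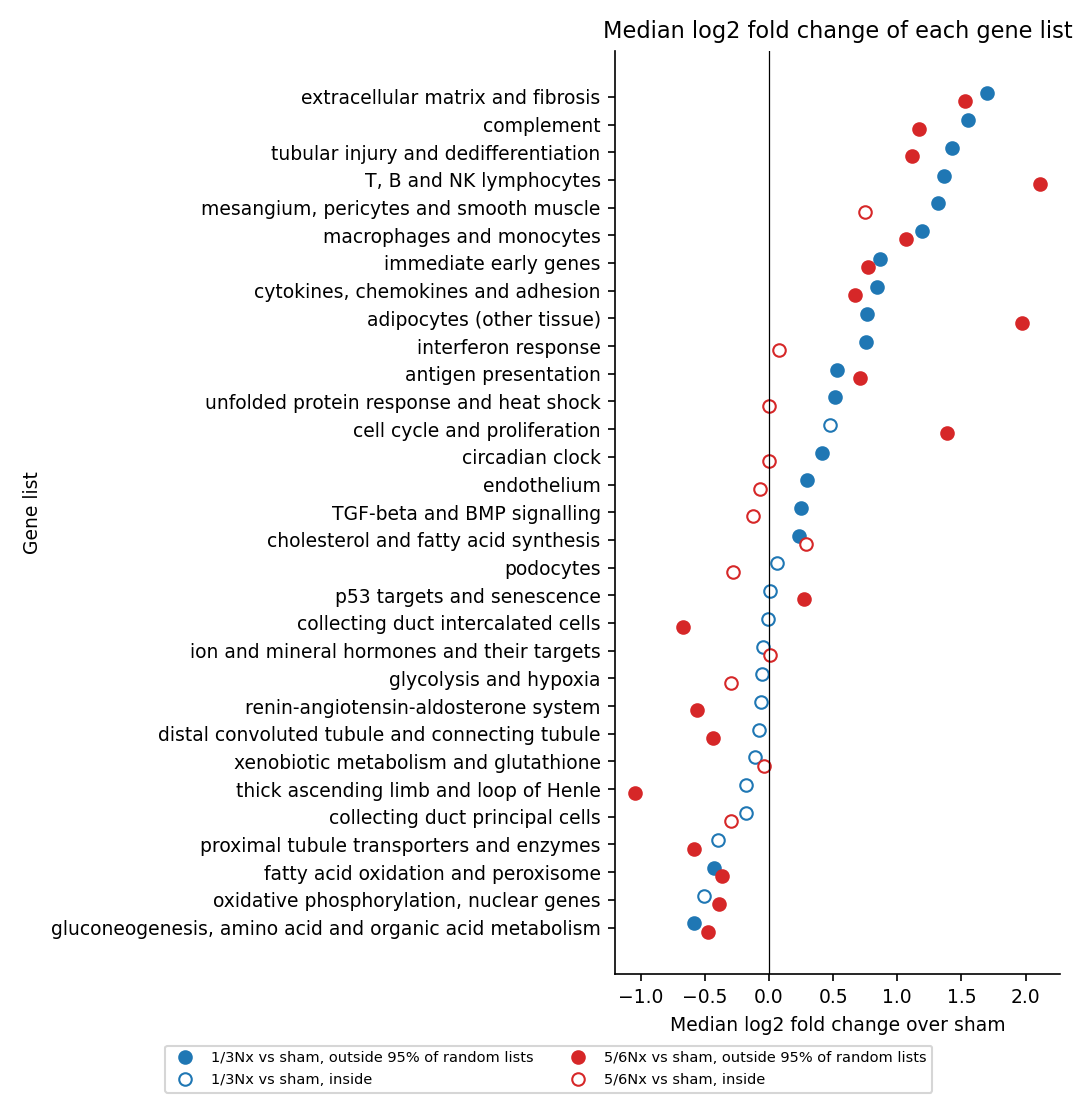
Median deposited log2 fold change over sham of the 31 gene lists measured in both tables, for 1/3Nx (blue) and 5/6Nx (red); filled points lie outside the middle 95% of 10000 random lists matched on mean FPKM. Matrix, complement, injury and lymphocyte lists lie to the right in both, and the thick ascending limb list lies furthest to the left, at -1.04, in 5/6Nx. The members of a list can differ between the tables, so the 2 points are not always over the same genes. The lymphocyte list had 9 members in 5/6Nx and 14 in 1/3Nx. Over the 8 compared in both tables its medians were 1.46 in 5/6Nx and 1.36 in 1/3Nx.

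The third comparison sets both surgeries side by side, which asks what losing the other kidney adds. Differences below are those of the deposited log2 fold changes, with no test of the difference. They use only members measured in both tables, so list sizes can differ from those given above. The median difference, 5/6Nx minus 1/3Nx, was -0.82 for thick ascending limb genes (3 of 16 higher in 5/6Nx), -0.68 for intercalated cell genes (0 of 12) and -0.72 for renin-angiotensin genes (2 of 10). The renin-angiotensin list shares Anpep and Mme with the proximal tubule list and Nr3c2 with the principal cell list, and is not independent of them. Its member Agt was above sham in 5/6Nx and below it in 1/3Nx, and passed in neither. The median difference was 0.84 for cell cycle genes (9 of 12 higher in 5/6Nx), 0.38 for p53 targets (9 of 16) and 0.73 for adipocyte markers (7 of 8). These 6 of 31 lists lay outside the random range, and matrix (-0.11), macrophage (0.01) and injury (0.27) lists did not. These results depended on the filter and the pseudocount. At a mean FPKM of at least 5 the adipocyte list lay inside and the cell cycle list had under 5 members. The injury (0.62), cholesterol (0.45), complement (-0.67), distal convoluted and connecting tubule (-0.50) and unfolded protein (-0.31) lists then lay outside. With no filter the adipocyte and p53 lists lay inside, and the interferon (-0.51), erythrocyte (-0.997) and skeletal muscle (0.89) lists lay outside. With a pseudocount of 1 the cell cycle difference was 0.55, and the TGF-beta list (-0.36) also lay outside. Cdkn1a had log2 fold changes of 3.25 in 5/6Nx and 0.75 in 1/3Nx, and Umod of -1.23 and -0.18, in the authors' deposited tables. Pgam2, a phosphoglycerate mutase gene, was called in opposite directions, at 2.66 in 5/6Nx and -1.41 in 1/3Nx in the authors' deposited tables, and was the only such gene among the 10378 tested in both.

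Across these 10378 genes, which had a mean of at least 1 FPKM in both tables and are not independent replicates, the deposited log2 fold changes had a Pearson correlation of 0.49 (0.44 to 0.54 over 1000 bootstrap draws of genes), a Spearman correlation of 0.21 and a covariance of 0.35. Of 272 genes higher in 5/6Nx and 493 higher in 1/3Nx, 52 were shared, against 12.9 for independent lists. Of 10 and 340 lower genes 5 were shared, against 0.328. Both comparisons use the same sham libraries, so a correlation above 0 and an excess of shared calls can arise with no effect of surgery. The shared controls could not be simulated or divided from group values, so no value under no change is known. The correlation of 0.49 is therefore not read as agreement between the surgeries, and the same limit holds for the shares of genes by direction below. Of the genes called higher in 1/3Nx, 91.5% had higher values in 5/6Nx as well, with median log2 fold changes of 1.20 in 1/3Nx and 1.14 in 5/6Nx. Of those called lower in 1/3Nx, 36.2% had higher values in 5/6Nx, with medians of -0.84 in 1/3Nx and -0.20 in 5/6Nx, where the median over all 10378 genes was -0.15.

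At the isoform level, 59840 isoforms passed in 5/6Nx (59724 higher, 116 lower) and 689 in 1/3Nx (426 higher, 263 lower), per the authors' deposited tables. Isoforms of named genes made up 787 of the former and 448 of the latter. Of these, 18 in 5/6Nx and 5 in 1/3Nx belonged to genes that were not called themselves.

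**Figure D4:**
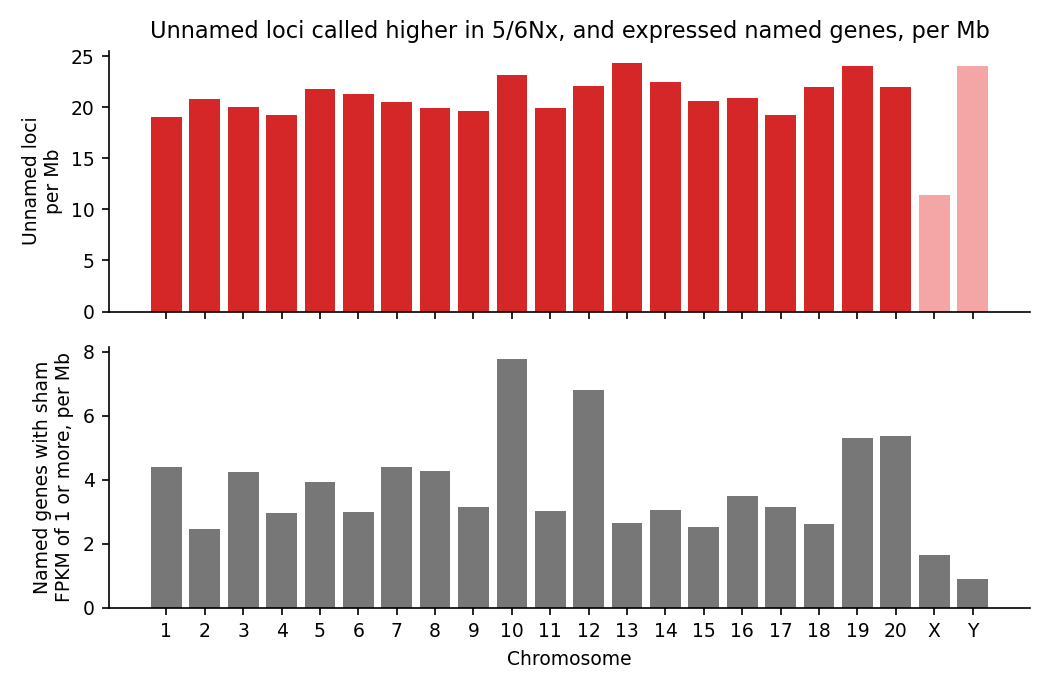
Top, number per Mb of unnamed loci listed at 0 in sham and called higher in 5/6Nx, by chromosome; bottom, named genes with at least 1 FPKM in sham per Mb, with chromosome lengths taken as the highest coordinate in the table. Loci lie between 19.0 and 24.3 per Mb on the 20 autosomes at 11.4 per Mb on X and at 24.1 per Mb on Y.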

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

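The tests of library measures between groups were chosen after the data were seen. Replicate 5 of 5/6Nx held 103.557 M reads and stood apart from the other 5 libraries of its group, which held 59.0 to 73.0 M reads; its gap to the next library was 0.685 of the group's range. It was the only library past the bound of this gap rule among 12 sets of values (4 measures in 3 groups), and chance marks about 1 in 20 such sets. The rule can miss a low library when a second one is also low. In mapping rate, replicate 3 of 5/6Nx (62.6%) had a gap of 0.523 of the range, under the bound of 0.625, with replicate 5 at 77.2%. No difference in mean read number was detected between 5/6Nx and sham (71.9 and 71.4 M reads, two-sided exact permutation p = 0.974, adjusted p = 0.974 over 12 tests). What the expression values are without replicate 5 was not analysed here.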

How the results depend on the processing

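Recomputing q-values over named genes, over genes of at least 1 FPKM or above 0 in sham, and over isoforms of named genes, and the pseudocount of 1, were chosen after the data were seen. The 60264 features called in 5/6Nx became 591 over features with 1 gene name, 35 with also at least 1 FPKM in sham, and 200 over features above 0 in sham; a mean FPKM of at least 1 or 5 left 56655 and 52662. The 1358 called in 1/3Nx became 762 at a mean FPKM of at least 5 and 862 over named genes with at least 1 FPKM in sham, where fewer features were tested, and 1146 to 1294 otherwise. Isoform calls moved from 59840 to 453 over named genes in 5/6Nx, and from 689 to 415 at a mean FPKM of at least 5 in 1/3Nx. The Pearson correlation across genes moved from 0.49 to 0.55 at a mean FPKM of at least 5, where the Spearman correlation went from 0.21 to 0.06, and to 0.37 with a pseudocount of 1; the cause was not tested. The number of lists outside the random range was 16 to 22 in 5/6Nx and 16 to 21 in 1/3Nx against 20 in each, and 6 to 9 against 6 for their difference, of which 4 of the 6 were kept at a mean FPKM of at least 5 and 4 with no filter. At a mean FPKM of at least 5, 16 of the 20 lists were kept in either surgery: the cytokine list in 5/6Nx and the cholesterol list in 1/3Nx lay inside, and the other 3 in each had under 5 members and were not placed. With no filter 18 of 20 were kept in 5/6Nx, without the lymphocyte and p53 lists and with the adrenal and principal cell lists added; the cell cycle list was added in 1/3Nx. A pseudocount of 1 added the cholesterol and mesangium lists in 5/6Nx. No paired analysis was possible because the expression tables hold 1 value per group. For the same reason alternatives fixed beforehand that need single libraries were not run: leaving out each library, library rescaling, quantile normalization, array weights, robust moderation, joint fits, estimated correlation, fry, divided sham libraries, and a pseudocount of 0.1 for the gene and isoform tests; nor were the test of 5/6Nx against 1/3Nx and each named gene under these alternatives. Depth per feature is unknown in these tables.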

Other observations

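The tests of marker lists in 5/6Nx, of the slope on expressed genes, of the density on Y, and of fold sizes and call rates were chosen after the result was seen; the other tests were written down before their results were seen.

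Endocrine pancreas, liver and plasma cell genes also moved in part. Of 14 islet genes, Chgb (log2 fold change 11.91), Gcg and Slc30a8 were called higher in 5/6Nx, per the authors' deposited table. Gcg and Slc30a8 are listed at 0 in sham, and Chgb had a recomputed q of 0.319 over named genes. The insulin genes Ins1 and Ins2 reached 6.15 and 4.99 FPKM in 5/6Nx without passing (both q = 0.306) in the authors' deposited table. The islet genes above 0, 13 in 5/6Nx and 10 in 1/3Nx, had medians of 8.72 and 3.03, counting those listed at 0 in sham (5 and 2) as highest. Of them 5 and 3 were tested. Among the 5 listed at 0 in sham, Iapp, Ppy and Pyy reached at most 0.167 FPKM in 5/6Nx. The finite values in 5/6Nx ran from -1.80 to 11.91, so the median does not show an even rise of islet genes. In 1/3Nx Ins1 was at 1.05 FPKM (q = 0.766), and 1 islet gene was called, Ttr, which liver also expresses, per the authors' deposited table. The albumin gene Alb rose from 1.19 to 39.0 FPKM in 1/3Nx (log2 fold change 5.04, q = 0.00183) and was at 0.553 FPKM against 0.590 in sham in 5/6Nx, per the authors' deposited tables. Of 9 plasma cell genes above 0 in 1/3Nx, Cd38 (1.64) and Pou2af1 (1.53) rose and Mzb1 (2.30, q = 0.0611) did not pass, in the authors' deposited table; in 5/6Nx 0 of the 6 tested passed. Their medians were 1.53 in 1/3Nx and 0.86 in 5/6Nx.

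Unnamed loci listed at 0 in sham made up 96.3% of the 5/6Nx calls and 64.5% of that group's summed FPKM. Loci per Mb hardly rose with expressed genes per Mb over the 20 autosomes (log-log slope 0.0587, 95% interval -0.0464 to 0.164), and of the 58038 loci 2865 were above 0 in 1/3Nx. Densities of whole chromosomes cannot show how near a locus lies to an expressed gene, and signal within the feature of a named gene is not counted. The slope therefore does not exclude transcription near expressed genes. Genomic DNA in some 5/6Nx libraries stays a candidate explanation, which copy number does not settle. Male rats carry 1 copy of X and of Y. Loci on X had 0.545 of the median autosomal density, where expressed genes had 0.4998 and named genes 0.856 of theirs, and loci on Y had 1.15. The 79 loci on Y, over 3.28 Mb, outnumbered those of each of 48 windows of that length on X, and repeats on Y could not be checked without the genome. No relation of density with named genes was detected (Spearman's rho -0.05, permutation p = 0.828). A low density on X without such a relation was the prediction written beforehand for genomic DNA, whereas the density on Y, a comparison added afterwards, was not low. Olfactory receptor features, mostly silent in kidney, were above 0 in 15.3% of cases in 5/6Nx and 5.92% in 1/3Nx, 9.42 percentage points apart. The short median span of 257 bp of the called loci may raise their FPKM. A further 16994 unnamed loci listed at 0 in sham were above 0 in 5/6Nx and not called, with a median span of 82.6 kb. Which libraries carry the called loci, and whether replicates 3 and 5 with their low mapping rates do, stays open, as does a biological difference of 5/6Nx.

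Most pancreatic enzyme genes were high in both surgery groups and under 1 FPKM in sham, except Cela1, Gp2 and Tmed6, with Prss1 at 179 FPKM against 0.226 in sham in 5/6Nx and 230 FPKM against 0.451 in 1/3Nx, where it did not pass (q = 0.180), per the authors' deposited tables. The acinar markers held out, of which 16 were above 0, had a median log2 fold change of 7.38 in 1/3Nx and 9.03 in 5/6Nx, counting the 4 listed at 0 in sham as highest. In 1/3Nx 3 of the 14 tested passed and in 5/6Nx 5 of 14, and several of the most abundant ones did not pass, such as Clps (69.0 FPKM, q = 0.562) in 1/3Nx, in the authors' deposited table. These counts rest on unlike thresholds, as the highest p-value called in the authors' test was 0.0032 in 1/3Nx and 0.02895 in 5/6Nx. Of the acinar risers in 5/6Nx, Pnliprp2, Erp27 and Pla2g1b passed at deposited q-values of 0.0186 to 0.0428. The held-out liver markers had a median of 2.599 in 1/3Nx and 0.59 in 5/6Nx, counting the 2 and 1 listed at 0 in sham as highest. In 1/3Nx 5 rose, 2 fell (Apoc3 and Serpinc1) and 9 of 27 were at 1 FPKM or more in sham. Among these risers Fgg (log2 fold change 2.94, q = 0.00471, in the authors' deposited table) is also in the injury list. In 5/6Nx 3 rose (F2, Fgg and Cps1) at deposited q-values of 0.00844 to 0.0183. Cacng5, with a deposited q of 0.00502 below those of these liver and acinar risers, had a recomputed q of 0.0663 over named genes. Pancreatic tissue in some samples of both surgery groups, and liver tissue in some 1/3Nx samples, are hypotheses these values are consistent with; how many animals carry them is open and no biological explanation was tested.

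Among named genes with at least 1 FPKM in sham, 171 were called in 5/6Nx and 820 in 1/3Nx, although the threshold on the p-value was more lenient in 5/6Nx. The cut of 1 FPKM was stricter in the 5/6Nx table, since sham values of the 1/3Nx table were 2.01 times as high. It left 10068 tested genes in 5/6Nx and 11259 in 1/3Nx. Whether smaller changes in 5/6Nx account for the fewer calls stays open. A fold change of 2 or more was found for 1137 genes there and 626 in 1/3Nx, a ratio of 1.82, which a larger spread would also raise. The median log2 fold change in 5/6Nx was 0.832 of that in 1/3Nx (95% interval over genes 0.745 to 0.908) for the 472 genes called higher in 1/3Nx and 0.239 (0.163 to 0.335) for 347 called lower. The latter had a median of -0.20 in 5/6Nx, as had all named genes of that table with at least 1 FPKM in sham. For the genes called in 5/6Nx it was 31.3 (16.99 to 157) for 161 higher and 2.38 (1.97 to 6.96) for 10 lower, and choosing genes by the calls of 1 table favours that table. At a log2 fold change of 1 to 2 in size, 2.31% (95% interval 1.498 to 3.54) were called in 5/6Nx and 65.1% (61.1 to 69.0) in 1/3Nx, a ratio of 0.0354. At a log2 fold change of 2 or more in size, 55.9% of 270 and 74.3% of 70 were called, in the same order. A larger spread between the 5/6Nx libraries is a possible explanation, which the group values do not show directly; whether it is technical or a difference between the animals is open.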
